A study of Mus musculus with 45 samples.

How the data were processed

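The series measured total RNA by stranded sequencing in primary mouse embryonic fibroblasts, a culture of connective-tissue cells taken from embryos. Each of 45 libraries belongs to 1 of 15 groups of 3 replicates, a full cross of 3 cell states with 5 treatments. The states were uninduced cells, cells brought to senescence with 200 µM hydrogen peroxide (H2O2) for 24 h and cells brought to senescence with 2 µM etoposide, an inhibitor of DNA topoisomerase II, for 24 h, both followed by 5 days of culture, per the labels' protocols. The treatments were the ethanol vehicle, alpha-eleostearic acid (ESA, a conjugated polyunsaturated fatty acid), its methyl ester (ESA-Me), and each compound after 1 h of ferrostatin-1 (Fer-1), an inhibitor of ferroptosis, at 2 µM. Cells were exposed to the compounds for 12 h. Per the labels of the samples, both compounds were given at 2 µg/mL, while the labels' treatment protocol gives 10 µg/mL for ESA and 20 µg/mL for ESA-Me, so the doses of the compounds may differ and no comparison between them is taken as dose-matched. The design has no group treated with Fer-1 alone.

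The deposited table holds raw integer read counts per gene for every library. Per the submitters' processing notes, the tools named are FastQC, HISAT2 2.1.0, featureCounts and edgeR with the GRCm38 mouse genome; the notes give neither their order nor their settings. The table lists 57010 gene identifiers, of which 21212 had no count in any library, and no library of the table was left out. Symbols came from the reference tables by identifier; 52029 identifiers were in GENCODE release M21 on GRCm38, and the 4981 others carried 0.275% of all counts. Coordinates in the report are those of GENCODE M21 on GRCm38. Because 147 symbols were carried by more than 1 identifier, tests were run per identifier. How the counting treated reads shared by near-identical genes is not stated, so values of Prl2c2, Prl2c3, Hspa1a, Hspa1b and Vmn2r79 are uncertain.

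Total counts per library, in megareads, ranged from 13.5 to 59.6 with a median of 22.7. The median was 27.9 in uninduced, 22.4 in H2O2-induced and 21.6 in etoposide-induced cells. TMM scaling factors lay between 0.94 and 1.07, mitochondrial transcripts took 0.879% to 2.21% of counts, and the 10 most abundant genes took 8.14% to 11% of them. No library was a copy of another of its group: over the 45 pairs within groups, the chi-square per gene between depth-scaled counts was 12 to 139.

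The comparisons, lists and rules below, except where stated, were chosen before the data were examined. Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 16194 genes with 99.95% of all counts. Counts were scaled with TMM, and 1 quasi-likelihood model with a coefficient for each of the 15 groups was fitted to all 45 libraries. There were 27 comparisons, 21 of them within a state and 4 of them tests of whether a compound's change differed between induced and uninduced cells. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Every gene's adjusted p is from edgeR's quasi-likelihood test and measures spread between these samples. Errors of log2 fold changes are standard errors, errors of CPM, the counts divided by the total counts in megareads, are standard deviations over n = 3 libraries, and CPM were computed from the deposited counts with TMM-scaled library sizes.

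Replicates carry the numbers 1 to 3 in each group. In all 21 comparisons within a state, libraries with the same number deviated from their group means together, with correlations across genes of 0.26 to 0.82 against at most 0.1 for libraries with different numbers. The pairing is thus read from the data and applies within a state; a replicate number is called a preparation below. The model with a preparation block nested in state, planned as the alternative, is therefore printed beside results where it changed a call or moved a count by more than 1.5 times, and it is named "with the block". Between uninduced and induced vehicle cells, same-number r was -0.22 to 0.05 (others up to 0.26), so senescence was not paired by number. Preparation number within state accounted for 42% of the variance of log2 CPM, state for 30.4% and treatment within state for 12.2%. The common dispersion was 0.0722 without the block and 0.0102 with it.

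The text names genes by a fixed rule. Among called genes with a mean CPM of at least 2 in at least 1 group compared, no overlap between the replicates of the groups compared, and a symbol that is not of a predicted or unnamed model, it takes the 8 highest and 8 lowest log2 fold changes for senescence, ESA and ESA-Me against vehicle, and the 4 highest and 4 lowest for other comparisons. Chance alone leaves 10% of unchanged genes without overlap between 3 and 3 libraries. The no-overlap condition was dropped for the tests of a difference between states. Members of the senescence and ferroptosis panels are always eligible, as are the 4 members of each other list with the smallest p.

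In all, 31 gene lists were fixed. They are the senescence panel, the ferroptosis panel, mitosis, DNA replication, p53 targets, secretory factors of senescence, ferroptosis drivers, ferroptosis defence, NRF2 targets, ATF4 and amino acid response, endoplasmic reticulum (ER) chaperones, heat shock, metallothioneins and metal response, cholesterol synthesis, fatty acid synthesis and desaturation, PPAR targets and fatty acid oxidation, iron handling, interferon response, extracellular matrix, contractile genes with SRF or YAP targets, lysosome, immediate early genes, glycolysis and hypoxia, the mitochondrial genome, and markers of macrophages, endothelium, epithelium, skeletal muscle, adipocytes, neural and glial cells and chondrocytes. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the 31 lists of a comparison. The test was repeated with the correlation estimated from the data, and its adjusted p is given where it ended a call. Members were also counted after adjustment over the list alone. Lists share members, for example Slc7a11 and Hmox1, so they are not independent of each other.

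Correlations and covariances of log2 fold changes across genes were computed between pairs of comparisons. Where the pair shared libraries, 20 simulations with no change gave the values that the shared libraries produce alone. The tests were run on simulated counts with 200 changed genes. Without the block, the ESA comparison of uninduced cells, run on 16194 genes, recovered 13.43%, 46.27% and 69.7% of genes changed by 0.5, 1 and 2 log2 units; with the block it recovered 46.27%, 77.61% and 89.39%, with 9 wrong calls.

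Alternatives planned in advance were RLE scaling factors, scaling by library size only, no filter on low counts, a model of the compared groups only, the Wald test of DESeq2 1.42.0, the block, and leaving out each library in turn. After the data were seen, DESeq2 with the block, the other scalings with the block, leaving out each library with the block, and a correction of each library for its trend on transcript GC content with the block were added. Intervals of the difference between ESA-Me and ESA use 95% of the t distribution with 24 residual degrees of freedom. The reads themselves were not analysed here.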

Results

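Gene expression was measured in primary mouse embryonic fibroblasts that were uninduced, or had been made senescent with H2O2 or etoposide, and were then exposed for 12 h to vehicle, ESA, ESA-Me, or either compound after Fer-1. Each of the 15 groups held 3 libraries, 45 in all. Total counts per library, in megareads, were 17 to 59.6 in uninduced, 15.4 to 38.8 in H2O2-induced and 13.5 to 34.4 in etoposide-induced cells. The first 3 principal components of log2 CPM held 32%, 20.3% and 17% of the variance. Uninduced libraries lay apart from induced ones on the first component, while libraries of the 2 inducers lay together by replicate number. Sex-linked transcripts marked the preparations. In uninduced cells, Xist, which is transcribed from the inactive X chromosome, was at most 0.0968 CPM in replicates 1 and 3 and 217 to 350 CPM in replicate 2. In H2O2-induced cells it was 214 to 307 CPM in replicate 1, at most 0.135 in replicate 2 and 478 to 664 in replicate 3. A replicate number therefore did not denote the same preparation in uninduced and induced cells.

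**Figure D1:**
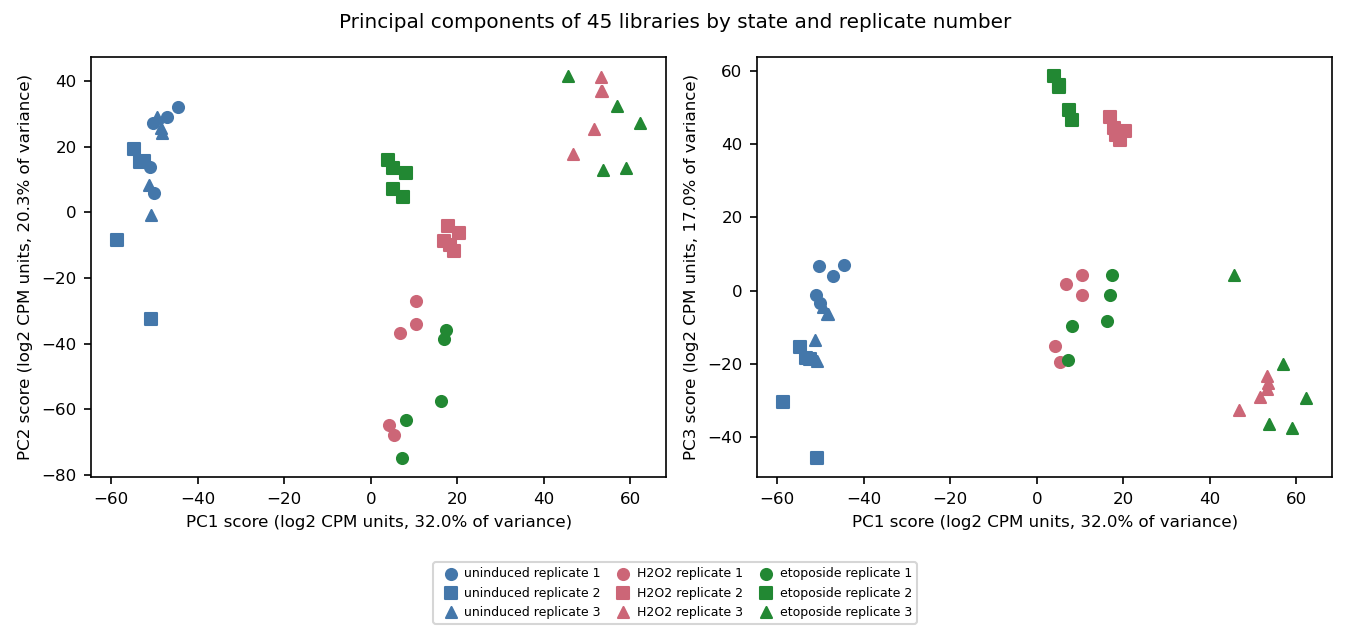
Principal component scores of the 45 libraries in log2 CPM units, with the first component on the x axis of both panels and the second (left) or the third (right) on the y axis; colours mark cell states and symbols replicate numbers. The first 3 components held 32%, 20.3% and 17% of the variance.

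The first question was what either inducer had changed in vehicle-treated cells. Slc38a4, which encodes an amino acid transporter (ENSMUSG00000022464, chromosome 15: 96994820 to 97055956 on GRCm38), fell from 98.0 ± 13 CPM in uninduced cells to 3.34 ± 0.961 CPM after H2O2 and 4.96 ± 4.45 CPM after etoposide (SD, n = 3). Its log2 fold changes were -4.86 ± 0.68 and -4.28 ± 0.66. The proliferation antigen gene Mki67 fell from 222 ± 27.3 to 16.9 ± 5.85 CPM after H2O2. The nuclear lamina gene Lmnb1 (ENSMUSG00000024590, chromosome 18: 56707813 to 56753424) fell by 2.82 ± 0.39 log2 units after H2O2 and by 2.67 ± 0.38 after etoposide. The cell cycle inhibitor gene Cdkn1a (ENSMUSG00000023067, chromosome 17: 29090976 to 29100727) rose from 369 ± 22.9 CPM to 888 ± 92.7 after H2O2 and 883 ± 280 after etoposide. Cdkn2a, which encodes p16 and p19ARF, rose from 43.9 ± 3.63 CPM to 120 ± 14.7 and 108 ± 21.9. Cdkn2b rose by 1.63 ± 0.23 and 1.58 ± 0.23 log2 units, and the chromatin protein gene Hmgb2 fell by 2.63 ± 0.48 and by 2.39 ± 0.47. Of the inflammatory members of the senescence panel, Il6 rose by 1.23 ± 0.38 (adjusted p = 0.0199) and 1.10 ± 0.38 (adjusted p = 0.0383). The matrix metalloproteinase gene Mmp3, at 4.74 ± 3.13 and 4.99 ± 3.09, did not pass.

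Among the highest fold changes were Svop, which encodes a synaptic vesicle protein (5.37 ± 1.23 after H2O2 and 5.27 ± 1.23 after etoposide), the NAD synthesis gene Nmnat2 (4.07 and 3.89) and Klhdc7a (4.05 and 3.87). The p53 target Perp (3.76 ± 0.66 and 3.82 ± 0.66), Fxyd6 (3.36 and 3.55), Pierce1 (3.25 and 3.06) and the microtubule-binding protein gene Map7 (3.10 ± 0.32 and 3.24 ± 0.32) also rose. Samd12 rose by 3.99 after H2O2 and Fam180a by 3.05 after etoposide. Among the lowest named fold changes were Kif2c (-3.68 and -3.27), Cenpa (-3.60 and -3.30) and Depdc1a (-3.54 and -3.66) after both inducers. The others were Pif1 (-3.82), Ska1 (-3.52) and the noncoding RNA Lockd (-4.05) after H2O2, and Ccnb2 (-3.61), Pclaf (-3.38), Bub1 (-3.36) and the lipid-binding protein gene Fabp7 (-3.77) after etoposide.

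All 20 measured mitosis genes fell after each inducer, with Aurka at -3.09 and -2.96, Cdc20 at -2.86 and -2.87 and Tpx2 at -2.37 and -2.34 (list adjusted p = 7.15e-16 and 1.74e-17). With an estimated correlation, the adjusted p of the mitosis list was 0.233 and 0.183. Of 22 DNA replication genes, 21 fell in each comparison, 21 and 22 adjusted over the list alone, among them Gins2 (-1.86 and -1.83), Mcm6 (-1.99 and -1.83) and Pcna (-1.07 and -0.97). This list also passed with an estimated correlation (adjusted p = 0.00474 and 0.00519). Of 20 p53 targets, 12 rose after H2O2 and 13 after etoposide, 14 and 13 adjusted over the list alone, including Ccng1 (0.97 and 0.83) and Phlda3 (0.85 and 0.87). The p53 list passed both ways (adjusted p = 0.00152 and 0.00238 with an estimated correlation). Of 20 lysosome genes, 16 rose in each comparison, 18 and 17 adjusted over the list alone, among them the protease gene Ctsd (1.23 and 1.18) and the proton pump subunit gene Atp6v0d1 (0.90 and 0.89). The lysosome list also passed both ways (adjusted p = 0.00193 and 0.00469 with an estimated correlation). Of 20 glycolysis and hypoxia genes, 12 and 11 fell, 14 and 13 adjusted over the list alone, with the lactate transporter gene Slc16a3 at -2.48 and -2.46 and Ldha at -1.15 and -1.08 (adjusted p = 0.0376 and 0.0423 with an estimated correlation).

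The ATF4 and amino acid response list passed as lower, with 9 of 26 members fallen in each comparison and, adjusted over the list alone, 9 fallen and 1 risen after H2O2 and 12 fallen after etoposide. Its fallen members included the serine synthesis gene Psat1 (-2.04 ± 0.27 and -1.94 ± 0.27) and Shmt2 (-1.24 and -1.25). Its adjusted p of 0.000199 and 0.000232 became 0.674 and 0.629 with an estimated correlation. Fatty acid synthesis and desaturation genes fell for 6 and 7 of 15 members, 7 and 7 adjusted over the list alone, including Scd1 (-1.03 and -1.02). Cholesterol synthesis genes fell for 6 and 4 of 24, including Stard4 (-1.12 and -1.29). Their adjusted p was 0.00342 and 0.00244 for fatty acid synthesis and 0.00834 and 0.0134 for cholesterol synthesis. With an estimated correlation these lists had adjusted p = 0.256 and 0.227, and 0.678 and 0.785. The epithelial marker list passed after H2O2 (2 of 3 fallen, Krt19 at -3.28; adjusted p = 0.0393, and adjusted p = 0.265 with an estimated correlation) and had adjusted p = 0.11 after etoposide, where 1 of 3 fell.

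Few genes of the ferroptosis panel changed between uninduced and induced vehicle cells. The ferritin heavy chain gene Fth1 rose by 0.50 ± 0.14 (adjusted p = 0.00844) and 0.61 ± 0.14 (adjusted p = 0.0016). Aifm2, which encodes the ferroptosis suppressor FSP1, passed after H2O2 (0.50 ± 0.17, adjusted p = 0.0361) but not after etoposide (0.41, adjusted p = 0.0912). Gpx4, the lipid hydroperoxide peroxidase gene (ENSMUSG00000075706, chromosome 10: 80047166 to 80056439), had log2 fold changes of 0.14 and 0.12. The cystine transporter gene Slc7a11 (ENSMUSG00000027737, chromosome 3: 49892526 to 50443614) was at -1.28 ± 0.68 and -1.70 ± 0.70, and the long-chain acyl-CoA synthetase gene Acsl4 at -0.33 and -0.62. None of these passed. Without the third library of etoposide vehicle, Acsl4 and Aifm2 passed in the etoposide comparison.

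Several lists had single members that passed without a call for the list, whose adjusted p after H2O2 and after etoposide is given last in each parenthesis below. Isg15 (1.78 and 1.81), Ifit1 (2.44 and 2.48) and Usp18 (2.53 and 2.32) rose and Ifit2 (-0.48 and -0.51) fell among 18 interferon response genes (adjusted p = 0.104 and 0.155 for the list). The metal-binding protein genes Mt1 (1.51 and 1.29) and Mt2 (2.12 and 1.76) rose among 6 metal response genes, 3 risen and 1 fallen (0.14 and 0.202). Of 19 secretory factors 2 rose (0.623 and 0.408), Il6 and the cytokine gene Lif, the latter by 1.86 and 2.18 log2 units. Of 25 PPAR targets and fatty acid oxidation genes 3 and 7 rose and 1 fell, including Fabp3 (1.51 and 1.54) and Acot1 (-1.51 and -2.03; 0.182 and 0.108). NRF2 targets had 3 risen and 1 fallen of 25 (Cbr3 1.04 and 1.10; 0.663 and 0.53), and iron genes 1 risen and 2 fallen of 15 (0.788 and 0.765). Ferroptosis defence genes had 2 and 1 risen and 2 fallen of 22, with the phospholipid acyltransferase gene Mboat1 at -2.08 and -1.96 (0.623 and 0.671). Ferroptosis drivers had 1 risen, Sat1 (1.14 and 1.24), and 1 and 2 fallen of 16 (0.873 and 0.771). The panels of 12 had 4 risen and 3 fallen in each comparison for senescence (0.713 and 0.765), and 2 and 1 risen for ferroptosis (0.788 and 0.902). ER chaperone genes had 4 fallen, among them Pdia6 (-0.60 and -0.55; 0.0513 and 0.191). Heat shock genes had 1 risen, Cryab (0.71 and 0.78), and 3 and 2 fallen of 17 (0.541 and 0.575). Of the cell type markers, 2 and 1 of 3 skeletal muscle genes fell, including Des (-1.57 and -1.50), 1 and 2 of 6 endothelial genes, including Emcn (-2.32 and -2.48), 0 and 1 of 6 neural genes, and 0 of the macrophage, adipocyte and chondrocyte genes (at least 0.0809 for these lists). Extracellular matrix genes had 0 and 2 of 18 fallen, the collagen genes Col1a1 (-0.77) and Col1a2 (-0.58) after etoposide (0.694 and 0.851). Among other lists, 0 passed of 15 contractile (0.623 and 0.287), 19 immediate early (0.781 and 0.408) and 13 mitochondrial genome genes (0.781 and 0.364).

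In all, 2834 of 16194 genes changed after H2O2 (1445 higher, 1389 lower) and 2873 after etoposide (1490 higher, 1383 lower). Both inducers had 1195 genes higher and 1171 lower, where independent lists would share 133 and 119. Across genes, which are not independent replicates, the log2 fold changes of the inducers correlated at r = 0.94 with a covariance of 0.436, against r = 0.49 and a covariance of 0.0733 simulated from the shared vehicle libraries alone. Those libraries are too few to split, and H2O2- and etoposide-induced vehicle libraries with the same number also deviated together (r = 0.62 to 0.76). Neither the simulation nor the independent counts include that second sharing, so part of the excess may come from either. Called directly against each other, the inducers differed in 0 genes by edgeR (99 at an unadjusted p under 0.05). They differed in 1 gene, Gm15506, named here after its values were seen, with a block on the replicate numbers the induced cells share. The counts fell to 1811 and 1828 without uninduced vehicle replicate 2 and to 1876 and 1843 with no filter on low counts, and that of etoposide to 1283 with a model of the compared groups alone. Il6 did not pass after H2O2 without H2O2 vehicle replicate 3 or uninduced vehicle replicate 1, and after etoposide without etoposide vehicle replicates 1 or 3 or uninduced vehicle replicate 1. After H2O2, the calls of Nmnat2 and Samd12 were lost without H2O2 vehicle replicate 3, and those of Depdc1a and Aifm2 without replicate 2. That of Aifm2 was also lost without H2O2 vehicle replicate 1 or uninduced vehicle replicates 2 or 3. After etoposide, the calls of Nmnat2 and Mki67 were lost without etoposide vehicle replicate 3, that of Mki67 also without replicate 1, and those of Nmnat2 and Fam180a without uninduced vehicle replicate 2. Uninduced and induced preparations with the same number differed in Xist. Each gave 5 correlated libraries to the spread estimate, so these p-values may be too small.

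ESA was next compared with vehicle in uninduced cells, to ask what the fatty acid alone changes. Values here are with the block. Hmox1, which encodes heme oxygenase 1 (ENSMUSG00000005413, chromosome 8: 75093621 to 75100589), rose from 103 ± 5.1 to 703 ± 575 CPM, a log2 fold change of 2.56 ± 0.34 (adjusted p = 5.81e-06; higher in 3 of 3 pairs). Slc7a11 rose from 15.3 ± 2.71 to 56.9 ± 8.8 CPM (1.92 ± 0.29) and the glutamate-cysteine ligase subunit gene Gclm by 1.62 ± 0.22 log2 units. The cyclooxygenase 2 gene Ptgs2 (ENSMUSG00000032487, chromosome 1: 150100031 to 150108227) rose from 242 ± 58.5 to 637 ± 147 CPM (1.40 ± 0.28). Gpx4 did not pass, at 181 ± 12.7 CPM with vehicle and 176 ± 24.3 CPM with ESA. Nor did Acsl4 (0.04), Aifm2 (0.19) or the glutathione-degrading enzyme gene Chac1 (0.43, adjusted p = 0.0545). The highest fold changes were of the protease inhibitor gene Serpinb2 (ENSMUSG00000062345, chromosome 1: 107511423 to 107535478; 5.10 ± 0.67, from 0.18 ± 0.099 to 7.44 ± 10 CPM), the molybdenum cofactor sulfurase gene Mocos (ENSMUSG00000039616, chromosome 18: 24653691 to 24701575; 2.64 ± 0.23) and the oxidative stress gene Osgin1 (2.56 ± 0.32). The SD of Serpinb2 with ESA was thus above its mean. Prl2c2 (3.85; 2.9 ± 3.62 CPM with ESA), Prl2c3 (3.79; 7.61 ± 9.02 CPM with ESA), Vmn2r79 (2.55) and the heat shock gene Hspa1a (2.41 ± 0.46) were also among the 8 highest. Reads of these may be shared with near-identical genes. The lowest were the gap junction gene Gja5 (-2.54 ± 0.34), Lrrc17 (-2.41 ± 0.33), Zbtb8b (-2.30) and the pentraxin gene Ptx3 (-2.23 ± 0.27). They also held the cartilage matrix gene Matn3 (-2.06), Palmd (-2.02), the G protein signalling regulator gene Rgs4 (-1.94) and Megf6 (-1.89).

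**Figure D2:**
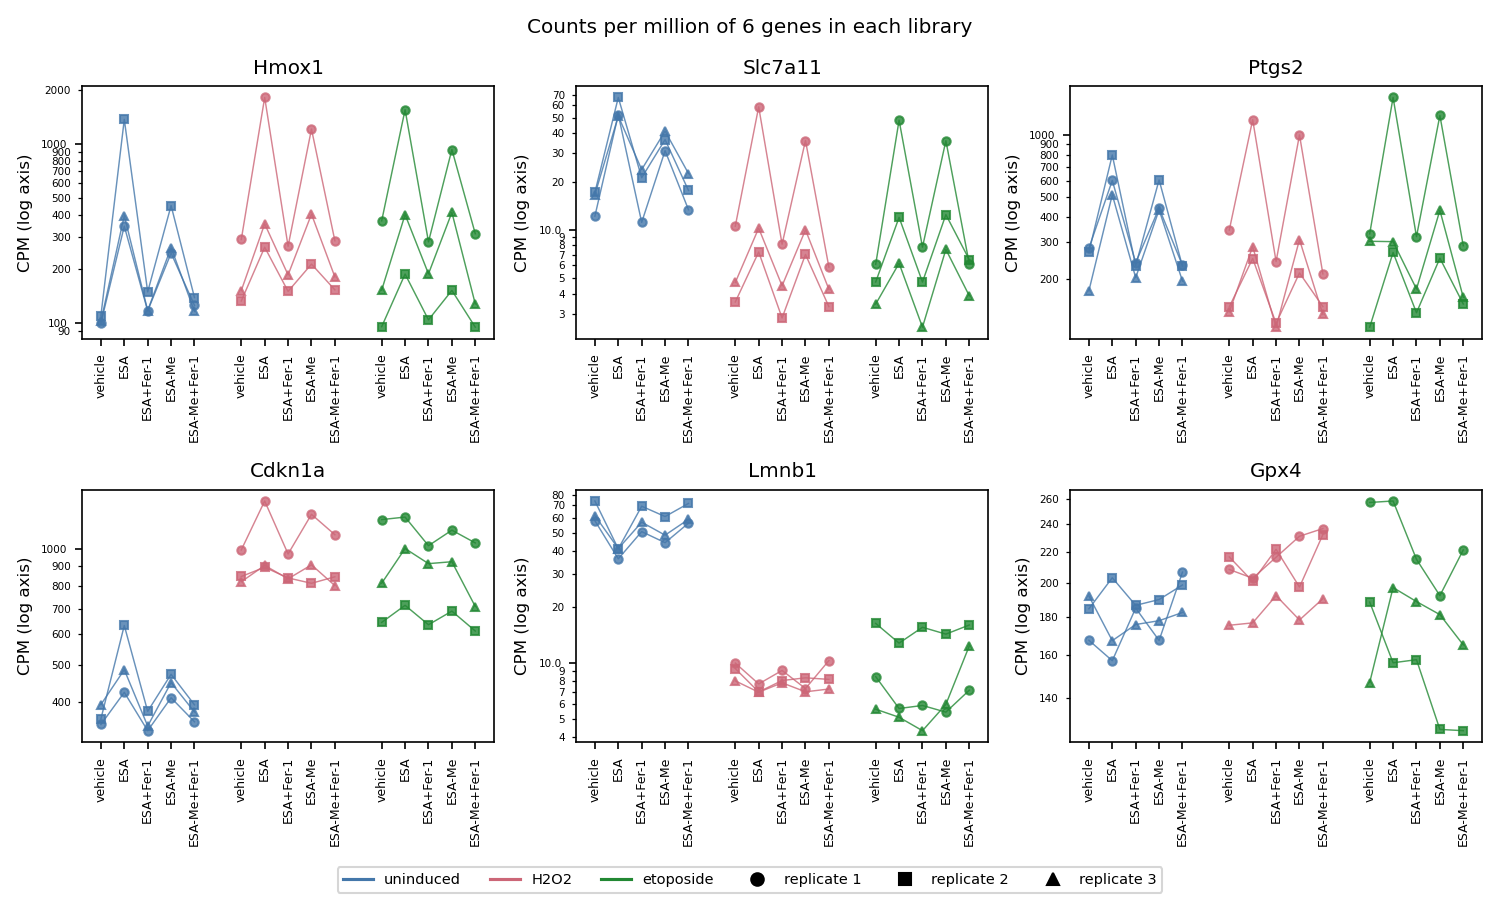
CPM on a log axis of Hmox1, Slc7a11, Ptgs2, Cdkn1a, Lmnb1 and Gpx4 in each library, by cell state and treatment on the x axis; points are libraries and lines join libraries with the same replicate number within a state. Hmox1 averaged 103 CPM with vehicle and 703 CPM with ESA in uninduced cells, and Gpx4 181 and 176 CPM.

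Of 25 NRF2 targets, 19 rose and none fell with ESA in uninduced cells, 20 adjusted over the list alone, including the sulfiredoxin gene Srxn1 (2.37 ± 0.24), the glutathione transferase gene Gsta4 (2.19), the autophagy receptor gene Sqstm1 (1.58) and Cbr3 (1.55). The adjusted p of the list was 1.04e-17, and 0.0521 with an estimated correlation. Of 26 genes of the ATF4 and amino acid response, 14 rose, 17 adjusted over the list alone, among them Atf3 (1.88), the stress cytokine gene Gdf15 (1.17 ± 0.13) and Nupr1 (0.54). This list had adjusted p = 1.1e-09, and adjusted p = 0.128 with an estimated correlation. Cholesterol synthesis genes fell for 20 of 24 members, 21 adjusted over the list alone, with the squalene synthase gene Fdft1 at -0.67, Cyp51 at -0.70 and Stard4 at -0.81 (adjusted p = 2.75e-12; adjusted p = 0.0521 with an estimated correlation). All 20 mitosis genes fell, among them Ccnb2 (-0.95) and Birc5 (-0.88), as did 14 of 22 DNA replication genes, 18 adjusted over the list alone, including Rrm1 (-0.60). Their adjusted p was 4.1e-09 and 2.95e-06, and 0.169 and 0.0815 with an estimated correlation. Immediate early genes rose for 10 of 19 members, 11 adjusted over the list alone, with Fosb at 2.38 and Fosl1 at 2.07 (adjusted p = 2.48e-08; adjusted p = 0.151 with an estimated correlation). Heat shock genes rose for 8 of 17, including Hspb8 (0.76) and Hspd1 (0.51), and metal response genes for 4 of 6. They had adjusted p = 1.05e-06 and 0.000935, and 0.0808 for both with an estimated correlation. The p53 target list passed both ways, with 6 of 20 members risen and 1 fallen (adjusted p = 0.0023, and 0.0419 with an estimated correlation), and Cdkn1a rose by 0.47 ± 0.09.

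Lists of genes tied to ferroptosis were read next, with the block. With ESA in uninduced cells, 12 of 22 ferroptosis defence genes rose and 3 fell, 13 and 3 adjusted over the list alone, including the thioredoxin reductase gene Txnrd1 (1.07) and the glutathione reductase gene Gsr (0.90). This list had adjusted p = 4.33e-06, and adjusted p = 0.128 with an estimated correlation. Of 16 ferroptosis drivers 5 rose and 2 fell (adjusted p = 0.103), and of 15 iron genes 5 rose (adjusted p = 0.0712). The ferroptosis panel of 12 had 7 risen, 8 risen and 1 fallen adjusted over the list alone, with adjusted p = 3.41e-06, or 0.0808 with an estimated correlation. In H2O2-induced and etoposide-induced cells, 3 and 1 defence genes rose with ESA, 8 and 8 adjusted over the list alone (adjusted p = 1.01e-05 and 1e-05). With an estimated correlation the adjusted p of that list was 0.119 and 0.138.

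With the block, 3213 genes changed with ESA in uninduced cells (1489 higher, 1724 lower). With a GC correction added to the block, chosen after the data were seen, 4372 did (2236 higher, 2136 lower), so the balance turned. Without the block 23 did by edgeR (20 higher, 3 lower), 177 by DESeq2, 65 with scaling by library size and 494 with a model of the compared groups alone. Of the 31 lists 13 passed without the block, none of them with an estimated correlation. Named among the highest without the block were Mocos (2.65 ± 0.38), Osgin1 (2.64 ± 0.53), Hspa1a (2.47), Fosb (2.38 ± 0.50), Ggct (1.59), Cbr3 (1.57), the necroptosis effector gene Mlkl (1.30) and Zfand2a (1.22). Among the lowest were Rxfp3 (-1.32), the insulin signalling gene Irs2 (-0.81) and Ssbp2 (-0.58). The 3213 became 1734 without vehicle replicate 2 and 1378 without ESA replicate 2. The 23 became 5, 4 and 6 without vehicle replicates 1, 2 and 3 and 5 without ESA replicate 2. Of the genes named without the block, Mocos alone kept its call without each of these 4 libraries, and Mlkl kept it without vehicle replicate 1.

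In senescent cells, the same comparison asked how induced fibroblasts responded to ESA. With the block, Slc7a11 rose in H2O2-induced cells from 6.27 ± 3.75 to 25.4 ± 28.8 CPM (1.72 ± 0.33, adjusted p = 0.00433). In etoposide-induced cells it rose from 4.76 ± 1.33 to 22.2 ± 22.9 CPM (1.83 ± 0.33, adjusted p = 0.00503), each time in 3 of 3 pairs. Hmox1 rose from 192 ± 87 to 810 ± 868 CPM (1.71 ± 0.33) and from 206 ± 145 to 712 ± 731 CPM (1.53 ± 0.33). The stress-responsive transcription factor gene Atf3 rose by 2.51 ± 0.32 and 2.24 ± 0.31 log2 units and the AP-1 subunit gene Fosb by 2.16 and 2.25 ± 0.32. Ptgs2 rose in H2O2-induced cells (1.24, adjusted p = 0.0184) and was at 1.15 in etoposide-induced cells (adjusted p = 0.0505). Chac1 rose after etoposide (0.67, adjusted p = 0.0441) and was at 0.53 after H2O2 (adjusted p = 0.0903). Gdf15 rose in both (0.54 and 0.98 ± 0.14) and Gpx4 passed in neither (-0.05 and 0.03). The other highest genes after H2O2 were Egr3 (2.15), the activity-regulated cytoskeletal gene Arc (2.08 ± 0.23), Hspa1a (1.83), the growth factor gene Ereg (1.47), Ankrd37 (1.42) and the phosphatase gene Dusp10 (1.40). The lowest were Nek2 (-1.27), Tk1 (-1.11), Mybl2 (-1.10), Bub1 (-1.09), Brip1 (-1.06), Prr11 (-0.99), Dtl (-0.96) and Clspn (-0.93). After etoposide, Hspa1a (2.32), Hspa1b (1.44), Vegfa (0.90), the lactate transporter gene Slc16a1 (0.85) and the sphingomyelin synthase gene Sgms2 (0.83) rose and Rrm1 (-0.48) and Ctps (-0.23) fell.

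Immediate early genes rose with ESA for 12 of 19 members in H2O2-induced and 11 of 19 in etoposide-induced cells, 18 and 18 adjusted over the list alone. They passed both ways (adjusted p = 8.65e-29 and 2.45e-26, and 0.0097 and 0.0286 with an estimated correlation). DNA replication genes fell for 4 and 2 of 22, 13 and 12 adjusted over the list alone, including Chaf1b (-0.77 and -0.70), also passing both ways (0.0097 and 0.0348 with an estimated correlation). The ATF4 and amino acid response rose for 9 and 6 of 26 members, 16 and 18 adjusted over the list alone, including Stc2 (1.31 and 0.91). Its adjusted p was 6.86e-18 and 1.36e-19, and with an estimated correlation 0.0531 after H2O2 and 0.0348 after etoposide. NRF2 targets rose for 7 and 3 of 25, 13 and 10 adjusted over the list alone, including Ugdh (0.63 and 0.66). For NRF2 the adjusted p was 2.06e-11 and 2.87e-08, and 0.0847 and 0.158 with an estimated correlation. Glycolysis and hypoxia genes rose for 7 and 5 of 20, 10 and 10 adjusted over the list alone, including the glucose transporter gene Slc2a1 (0.85 and 0.84) and Ankrd37 (1.42 and 1.14). Here the adjusted p was 5.1e-11 and 1.37e-11, and 0.0764 and 0.0545 with an estimated correlation. Mitosis genes fell for 6 and 1 of 20, 18 and 4 adjusted over the list alone, including Birc5 (-0.92 and -0.85). Mitosis had adjusted p = 8.48e-19 and 1.37e-11, and 0.0764 and 0.138 with an estimated correlation. The cholesterol synthesis list, with 0 of 24 members passed in either state, was lower after H2O2 (adjusted p = 0.00372; adjusted p = 0.327 with an estimated correlation) and had adjusted p = 0.144 after etoposide.

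With the block, 240 genes changed with ESA in H2O2-induced cells (195 higher, 45 lower) and 99 in etoposide-induced cells (89 higher, 10 lower). With the GC correction added these were 501 (374 higher, 127 lower) and 232 (197 higher, 35 lower), and by DESeq2 with the block 385 and 180. Without the block edgeR called 0 in each, with 440 and 475 at an unadjusted p under 0.05, and DESeq2 called 2 and 3. Of 31 lists 14 and 12 passed without the block, 0 and 0 of them with an estimated correlation. Without 1 library, the 240 became 12 to 392 (12 without ESA replicate 1) and the 99 became 7 to 1296 (7 without ESA replicate 1, 1296 without vehicle replicate 3). The unblocked 0 after etoposide became 4 without ESA replicate 2. Etoposide vehicle libraries differed in how their log2 CPM followed transcript GC content, with a correlation across genes of 0.49 in replicate 1 and -0.25 in replicate 3, against 0.44 in etoposide ESA replicate 3.

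Whether ESA changed a gene by a different amount in senescent than in uninduced cells was tested as an interaction, with the block. Mocos responded less in H2O2-induced cells by -2.44 ± 0.32 log2 units (adjusted p = 0.00018) and in etoposide-induced cells by -2.15 ± 0.32 (adjusted p = 0.00111). The NRF2 targets Gsta4 (-1.88 ± 0.37 and -1.91 ± 0.38), Srxn1 (-1.44 ± 0.33 and -1.54 ± 0.33) and Cbr3 (-1.19 ± 0.25 and -1.21 ± 0.25) were also lower in their response in both states. The differences of Slc7a11 (-0.19 ± 0.44 and -0.08 ± 0.44) and Hmox1 (-0.85 ± 0.46 and -1.03 ± 0.46) did not pass. Of 25 NRF2 targets, 3 and 4 had a lower response and none a higher one, 8 and 11 adjusted over the list alone. The list had adjusted p = 3.08e-11 and 7.46e-11, and 0.196 and 0.264 with an estimated correlation. Cholesterol synthesis genes, which fell in uninduced cells, had differences above 0 as a list, with 0 and 1 of 24 members passed, 9 and 14 adjusted over the list alone, and Fdft1 at 0.60 ± 0.15 in etoposide-induced cells. Their adjusted p was 1.86e-11 and 1.47e-11, and 0.148 and 0.155 with an estimated correlation. Not every list responded less in induced cells. Immediate early genes had differences above 0 as a list for H2O2 (0 of 19 members passed, adjusted p = 0.0133; adjusted p = 0.567 with an estimated correlation) and no call for etoposide (adjusted p = 0.159). Glycolysis and hypoxia genes also lay above 0, with 0 and 1 of 20 members passed, adjusted p = 0.00219 and 0.00736, and 0.388 and 0.583 with an estimated correlation. The interaction called 42 genes for H2O2 (6 above 0, 36 below) and 120 for etoposide (28 above, 92 below), with the GC correction added 133 (33 above, 100 below) and 365 (126 above, 239 below), and by DESeq2 with the block 89 and 187. Without the block edgeR called 0 and 0, with 221 and 382 at an unadjusted p under 0.05, and DESeq2 1 and 2. Without 1 library, the 42 became 1 to 64 and the 120 became 6 to 521, each lowest without uninduced ESA replicate 2.

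The methyl ester ESA-Me was then compared with vehicle, again with the block. In uninduced cells, Slc7a11 rose from 15.3 ± 2.71 to 36.4 ± 5.06 CPM (1.26 ± 0.29, adjusted p = 0.0223) and Hmox1 from 103 ± 5.1 to 319 ± 114 CPM (1.55 ± 0.33, adjusted p = 0.0127). Gclm rose by 0.87 log2 units, Ptgs2 by 1.04 (adjusted p = 0.0493), Gdf15 by 0.64 and the transferrin receptor gene Tfrc by 0.69, while the acyl-CoA synthetase gene Acsl1 fell by 0.32 and Gpx4 was at -0.03. Serpinb2 (3.81 ± 0.71), Dusp2 (1.91), Fam110c (1.63), Esm1 (1.60), the lipase inhibitor gene Angptl4 (1.58) and Fosb (1.56) had the highest fold changes, with Prl2c3 (2.41) and Vmn2r79 (1.83). Lrrc17 (-1.53), Megf6 (-1.51), Palmd (-1.51), Ptx3 (-1.44), Gprin3 (-1.25), Clmn (-1.12), the calcium channel gene Cacna1a (-1.07) and Rtl3 (-1.06) had the lowest. In H2O2-induced cells Atf3 (2.15 ± 0.32), Arc (2.04 ± 0.23), Fosb (1.97), Tmem95 (1.55), Ankrd37 (1.36), Dusp10 (1.33), Ereg (1.24) and the receptor feedback inhibitor gene Errfi1 (1.15) rose. Slc7a11 (1.35), Hmox1 (1.41) and Ptgs2 (1.11) rose too, and Ccne2 (-0.96), Dtl (-0.90), Usp49 (-0.60), Tmtc4 (-0.41) and Wdr7 (-0.29) fell. In etoposide-induced cells Fosb (1.83), Slc7a11 (1.72 ± 0.34, adjusted p = 0.0118), the chromatin protein gene Hmga2 (0.93), Cd44 (0.88), Sgms2 (0.79), Zfp36l2 (0.77), Fgf2 (0.68) and Tgif1 (0.66) rose. There, Hmox1 (1.16, adjusted p = 0.121) and Ptgs2 (1.13, adjusted p = 0.0746) did not pass.

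Immediate early genes rose with ESA-Me for 5, 12 and 6 of 19 members in uninduced, H2O2-induced and etoposide-induced cells, 9, 17 and 15 adjusted over the list alone (adjusted p = 3.33e-09, 2.36e-25 and 7.68e-19). With an estimated correlation the list passed in H2O2-induced cells (adjusted p = 0.0343) and not in the others (adjusted p = 0.138 and 0.122). NRF2 targets rose for 9, 2 and 1 of 25 members, 14, 8 and 3 adjusted over the list alone, including Srxn1 (1.31) and Gsta4 (1.42) in uninduced cells. Their adjusted p was 4.24e-15, 5.24e-09 and 0.0157, and 0.0751, 0.172 and 0.541 with an estimated correlation. The ATF4 and amino acid response rose for 3, 5 and 2 of 26, 7, 13 and 6 adjusted over the list alone. It had adjusted p = 1.3e-07, 2.06e-13 and 4.59e-07, and 0.146, 0.111 and 0.368 with an estimated correlation. In uninduced cells the cholesterol synthesis list was lower, with Fdft1 (-0.42) the 1 member of 24 that passed, 13 adjusted over the list alone. Its adjusted p was 9.33e-10, or 0.0751 with an estimated correlation.

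With the block, 266 genes changed with ESA-Me in uninduced (164 higher, 102 lower), 147 in H2O2-induced (124 higher, 23 lower) and 46 in etoposide-induced cells (44 higher, 2 lower). With the GC correction added these were 692 (420 higher, 272 lower), 314 (235 higher, 79 lower) and 201 (182 higher, 19 lower), and by DESeq2 with the block 403, 267 and 126. Without the block edgeR called 0 in each state, with 358, 382 and 545 at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 1. A model of the compared groups alone called 46 in uninduced cells. Of 31 lists 12, 13 and 9 passed without the block, and 1, 0 and 0 with an estimated correlation. Without 1 library, the 266 became 3 to 149 (3 without vehicle replicate 2), the 147 became 4 to 339 (4 without vehicle replicate 1) and the 46 became 0 to 3321 (0 without vehicle replicate 1 or ESA-Me replicate 3, 3321 without vehicle replicate 3). No gene differed in its response to ESA-Me between induced and uninduced cells, with or without the block. For this difference edgeR called 0 for H2O2 (88 at an unadjusted p under 0.05, 445 with the block) and 0 for etoposide (156 and 792), and DESeq2 called 0 in each.

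ESA and ESA-Me, which differ by the methyl ester, were compared directly, with the reservation that their doses may differ. In uninduced cells the response to ESA-Me was smaller for Hmox1 by -1.01 ± 0.32 log2 units (95% interval -1.67 to -0.35, adjusted p = 0.263) and Slc7a11 by -0.66 ± 0.28 (-1.24 to -0.08, adjusted p = 0.435). Gclm differed by -0.75 ± 0.22 and Srxn1 by -1.06 ± 0.23 (-1.53 to -0.59). None of these passed over all genes, and for Ptgs2 the interval was -0.92 to 0.20. With the block, 3 genes passed, all lower with ESA-Me: Mocos (-1.27 ± 0.21, adjusted p = 0.0119), Mlkl (-0.64 ± 0.12) and the microtubule-associated protein gene Map1a (-0.59 ± 0.11, both adjusted p = 0.0296). With the GC correction added to the block, 97 genes passed, 21 higher and 76 lower with ESA-Me, and these 3 were among them. The NRF2 list was lower with ESA-Me, with 0 of 25 members passed, 15 adjusted over the list alone. Its difference had adjusted p = 3.78e-14, or 0.161 with an estimated correlation. In H2O2-induced and etoposide-induced cells, the difference of Slc7a11 was -0.37 ± 0.30 (95% interval -0.99 to 0.25) and -0.11 ± 0.30 (-0.73 to 0.51). That of Hmox1 was -0.30 ± 0.32 (-0.96 to 0.36) and -0.36 ± 0.32 (-1.02 to 0.30). Without the block edgeR called 0 genes in uninduced, H2O2-induced and etoposide-induced cells (at most 219 in each state at an unadjusted p under 0.05), and DESeq2 called 0 in each. With the block the induced states also had 0 (288 and 720 at an unadjusted p under 0.05). Across genes, the log2 fold changes of the compounds against their shared vehicle correlated at r = 0.80, 0.74 and 0.62 in the 3 states, against 0.51, 0.49 and 0.46 simulated from the shared vehicle alone. The covariances were 0.101, 0.0676 and 0.0565 against simulated 0.0255, 0.0271 and 0.0276. With the block, 162, 103 and 35 genes were higher with both, where independent lists would share 15.1, 1.49 and 0.242. The vehicle libraries are too few to split, so part of the excess may come from them.

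**Figure D3:**
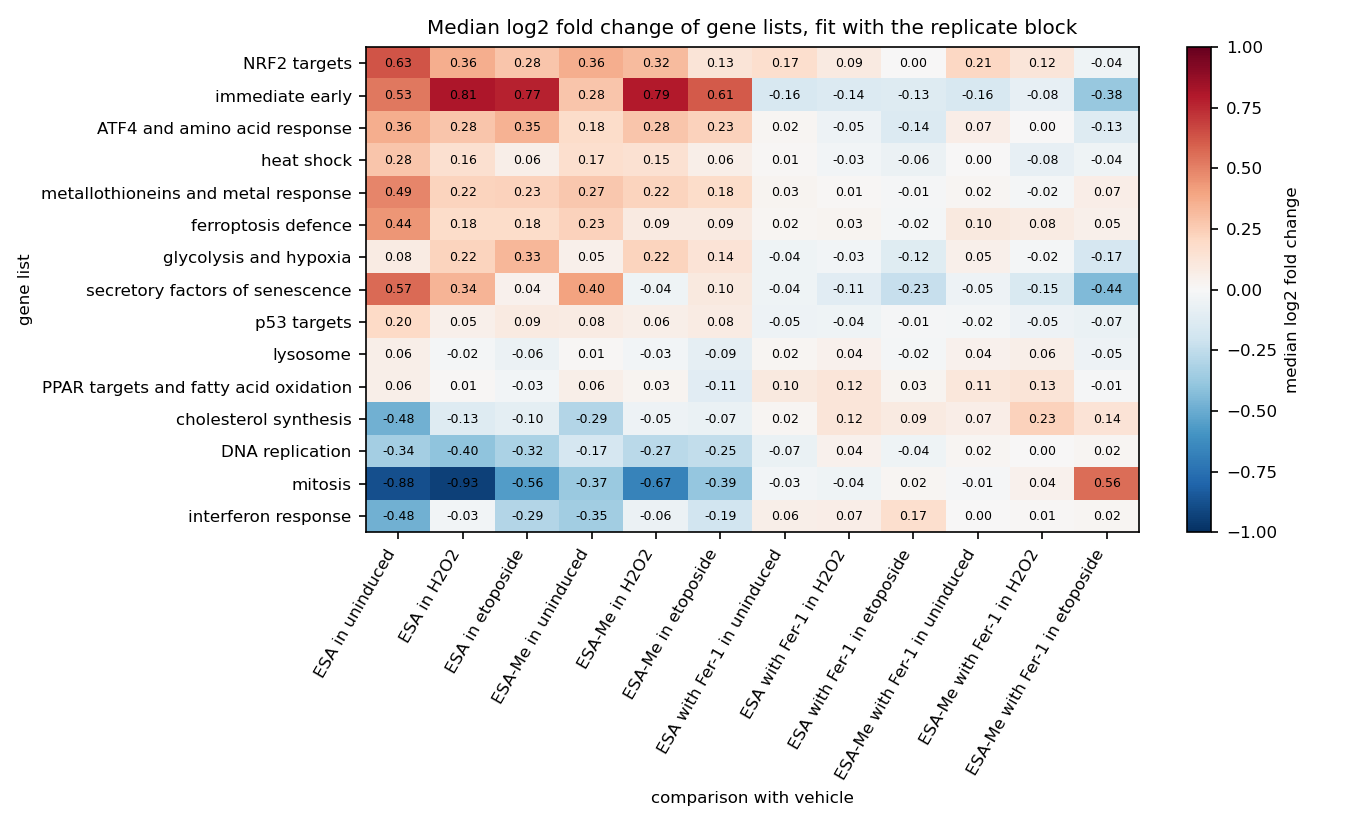
Median log2 fold change of gene lists (y axis) in each comparison with vehicle (x axis), from the fit with the block; the colour scale runs from -1 to 1. For immediate early genes the median was 0.81 with ESA and -0.14 with ESA and Fer-1 in H2O2-induced cells.

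Fer-1 pretreatment was compared with the compound alone to ask which changes it opposed; values are with the block. In uninduced cells, Fer-1 lowered Hmox1 under ESA from 703 ± 575 to 127 ± 18.4 CPM (-2.28 ± 0.34) and Slc7a11 from 56.9 ± 8.8 to 18.7 ± 6.68 CPM (-1.66 ± 0.29). Ptgs2 fell by 1.48 ± 0.28 and Gclm by 1.34 log2 units. Slc7a11 fell by 1.98 ± 0.33 log2 units in H2O2-induced and by 1.89 ± 0.35 in etoposide-induced cells, and Hmox1 fell by 1.56 ± 0.33 and by 1.49 ± 0.33. The lowest named genes were Serpinb2 (-4.26 ± 0.63), Ngef (-2.74), Mocos (-2.73) and Prl2c3 (-2.54) in uninduced cells. They were Atf3 (-2.88 ± 0.32), Egr3 (-2.76), Fosb (-2.48) and Arc (-2.39) in H2O2-induced cells, and Fosb (-2.28), the desmosome gene Pkp1 (-2.14), Nr4a3 (-2.12) and Hspa1a (-2.11) in etoposide-induced cells. Among the highest were Ptx3 (2.25), Lrrc17 (2.12) and Palmd (2.09) in uninduced cells. The highest were Tk1 (1.21), Mybl2 (1.09), Pclaf (1.08) and Nek2 (1.03) in H2O2-induced, and Zfp78 (0.75), Chaf1b (0.72), Gins3 (0.56) and Asb13 (0.54) in etoposide-induced cells.

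Immediate early genes fell with Fer-1 added to ESA for 13, 17 and 14 of 19 members in uninduced, H2O2-induced and etoposide-induced cells, 14, 18 and 18 adjusted over the list alone. Their adjusted p was 2.29e-11, 1.02e-29 and 3.83e-26, and with an estimated correlation 0.103, 0.0129 and 0.0269. The ATF4 and amino acid response fell for 16, 14 and 14 of 26 members, 21, 18 and 25 adjusted over the list alone, including the arginine transporter gene Slc7a1 (-0.54, -0.56 and -0.60). For this list the adjusted p was 2.79e-09, 3.5e-18 and 4.72e-23, and 0.131, 0.045 and 0.0269 with an estimated correlation. In uninduced cells cholesterol synthesis genes rose for 20 of 24 members, 22 adjusted over the list alone (Fdft1 0.66, Cyp51 0.76). They passed both ways (adjusted p = 8.01e-13, and 0.038 with an estimated correlation). NRF2 targets fell for 18 of 25 there, 19 adjusted over the list alone, with Srxn1 at -2.00 (adjusted p = 3.63e-12; adjusted p = 0.0962 with an estimated correlation). Mitosis genes rose for 19 of 20, 20 adjusted over the list alone (adjusted p = 3.38e-08; adjusted p = 0.164 with an estimated correlation). The p53 target list passed both ways with 7 members fallen and 1 risen (adjusted p = 9.54e-05, and 0.00326 with an estimated correlation). In H2O2-induced cells DNA replication genes rose for 7 of 22, 17 adjusted over the list alone, passing both ways (adjusted p = 4.97e-13, and 0.0129 with an estimated correlation). Mitosis genes rose for 7 of 20, 17 adjusted over the list alone (adjusted p = 7.01e-14; adjusted p = 0.0879 with an estimated correlation).

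With the block, Fer-1 added to ESA changed 3250 genes in uninduced (1688 higher, 1562 lower), 677 in H2O2-induced (184 higher, 493 lower) and 383 in etoposide-induced cells (73 higher, 310 lower). With the GC correction added these were 4416 (2126 higher, 2290 lower), 1375 (480 higher, 895 lower) and 799 (241 higher, 558 lower). Without the block edgeR called 29, 3 and 0, with 714 at an unadjusted p under 0.05 beside the 0, and DESeq2 called 124, 18 and 10. A model of the compared groups alone called 309 in uninduced and 0 in H2O2-induced cells. The 29 included Fgfr3 (1.46), Rxfp3 (1.24), the inhibitor of differentiation gene Id2 (0.89), Acsl3 (0.76), Mocos (-2.75, adjusted p = 0.000555), Fosb (-2.50), Osgin1 (-2.40) and Ereg (-1.85). The 3 were Fosb (-2.63, adjusted p = 0.0462), Ereg (-2.14) and Sgms2 (-0.90, both adjusted p = 0.0348). Without 1 library, the 3250 became 1513 to 3039 (1513 without ESA replicate 2), the 677 became 62 to 836 (62 without ESA replicate 1) and the 383 became 50 to 535 (50 without replicate 1 of ESA with Fer-1). Without the block, the 29 became 2 to 16, the 3 became 0 to 7 and the 0 of etoposide-induced cells became 0 to 10.

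Added to ESA-Me, Fer-1 lowered Slc7a11 (-1.05, -1.78 and -1.52 log2 units) and Hmox1 (-1.27, -1.25 and -1.32) in uninduced, H2O2-induced and etoposide-induced cells, with the block. Fosb was among the 4 lowest genes in each state (-2.14, -2.04 and -2.30). With it were Dusp2 (-1.98), Vmn2r79 (-1.71) and the semaphorin gene Sema7a (-1.66) in uninduced, Atf3 (-2.28), Tmem95 (-2.08) and Hspa1a (-1.93) in H2O2-induced, and Atf3 (-2.41), Egr3 (-2.39) and Pkp1 (-2.27) in etoposide-induced cells. The highest were Palmd (1.47), Ptx3 (1.39), Slc6a12 (1.32) and Lrrc17 (1.28), the DNA repair gene Fancd2 (2.29-fold), Dtl (1.02), Naprt (0.79) and Chtf18 (0.76), and Rab27a (1.83), Rapsn (0.99), Rab40b (0.94) and Ypel1 (0.87) in the same order of states. Immediate early genes fell for 7, 13 and 17 of 19 members, 13, 18 and 18 adjusted over the list alone. They had adjusted p = 1.63e-14, 1.48e-25 and 4.66e-30, and 0.0516, 0.033 and 0.0148 with an estimated correlation. Cholesterol synthesis genes rose for 8 of 24 in uninduced cells, 18 adjusted over the list alone, passing both ways (adjusted p = 1.24e-13, and 0.0223 with an estimated correlation). In etoposide-induced cells 15 of 20 mitosis genes rose, 19 adjusted over the list alone (adjusted p = 3.92e-16; adjusted p = 0.109 with an estimated correlation). Over the pairs, their mean change from vehicle with ESA-Me and Fer-1 was 0.49, 0.1 and 1.04, the last in a library that stands apart. This replicate 3 of ESA-Me with Fer-1 carried 92.7 CPM of 4 summed Y-linked genes while the other 4 libraries of its preparation carried 0, and without it the comparison called 100 genes in place of 720.

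Fer-1 added to ESA-Me changed 596 genes in uninduced (282 higher, 314 lower), 344 in H2O2-induced (72 higher, 272 lower) and 720 in etoposide-induced cells (291 higher, 429 lower) with the block, and 1204, 766 and 1339 with the GC correction added. Without the block edgeR called 0, 0 and 1, the last being the kinase gene Nuak2 (-0.75 ± 0.12, adjusted p = 0.00648). Beside the 0 counts, 476 and 573 were at an unadjusted p under 0.05, and DESeq2 called 0, 4 and 4. Without 1 library, the 596 became 69 to 278 (69 without ESA-Me replicate 2), the 344 became 24 to 464 (24 without replicate 1 of ESA-Me with Fer-1) and the 720 became 100 to 1083 (100 and 1083 without replicates 3 and 2 of ESA-Me with Fer-1). The call of Nuak2 became 0 genes without ESA-Me replicates 1 or 3 or replicates 2 or 3 of ESA-Me with Fer-1, and 6 genes without ESA-Me replicate 2.

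**Figure D4:**
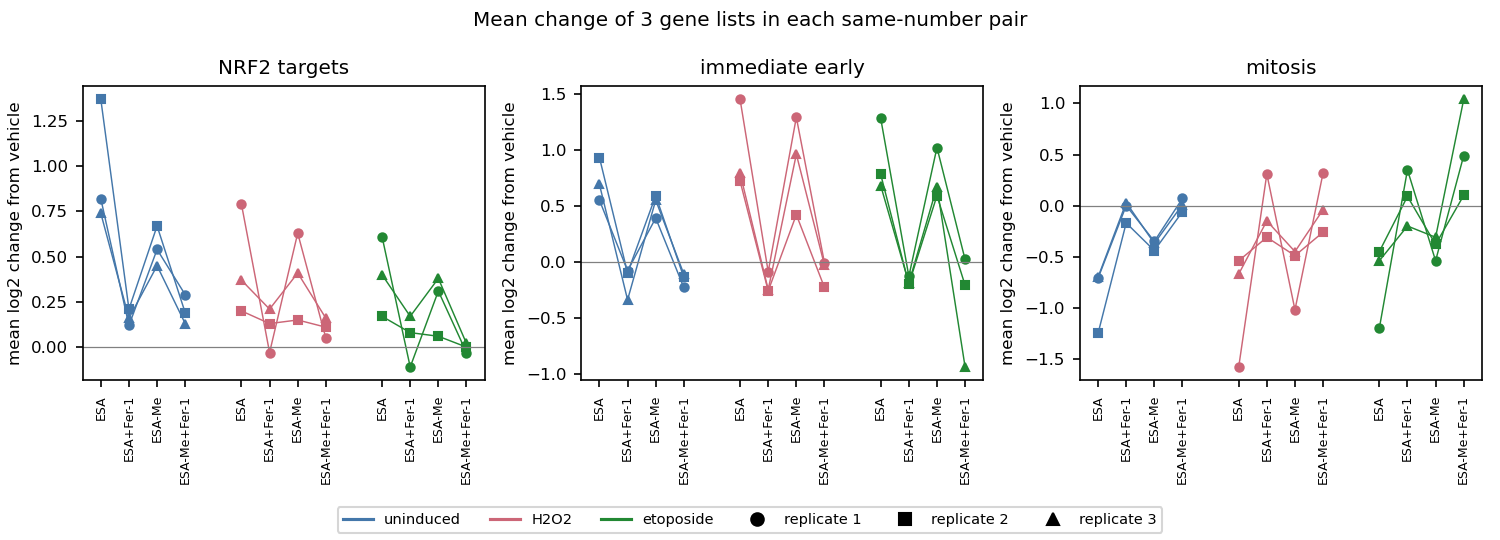
Mean log2 change from vehicle (y axis) of NRF2 targets, immediate early genes and mitosis genes in each same-number pair of libraries, by cell state and treatment (x axis). For NRF2 targets with ESA, the pairs were at 0.82, 1.37 and 0.74 in uninduced and 0.79, 0.2 and 0.37 in H2O2-induced cells.

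Cells that received a compound after Fer-1 were finally compared with vehicle. Slc7a11 in uninduced cells was at 18.7 ± 6.68 CPM with ESA and Fer-1 against 15.3 ± 2.71 CPM with vehicle (0.26 ± 0.30 with the block), and Hmox1 at 127 ± 18.4 against 103 ± 5.1 CPM (0.28 ± 0.32). Of the 1489 genes higher with ESA in uninduced cells, 1485 had a fold change of opposite sign when Fer-1 was added and 1166 were called so. Their median log2 change against vehicle was 0.48 without and 0.01 with Fer-1. For the 1724 lower genes these were 1721, 1277, -0.59 and -0.04. Of the 195 and 89 genes higher with ESA after H2O2 and etoposide, 174 and 82 were called back, with medians of 0.70 and 0.79 without and -0.06 and -0.11 with Fer-1, and of the 45 and 10 lower genes 34 and 5. Of the 164, 124 and 44 higher with ESA-Me in the 3 states, 115, 106 and 42 were called back, and of the 102, 23 and 2 lower 69, 8 and 1. The genes share the compound libraries between these comparisons, which alone yields opposite signs. The correlation of the ESA response with the change on adding Fer-1 was -0.86, -0.78 and -0.72 in uninduced, H2O2-induced and etoposide-induced cells against simulated -0.48, -0.52 and -0.49. The covariance was -0.162, -0.0765 and -0.0754 against simulated -0.026, -0.0285 and -0.0297. For ESA-Me the correlations were -0.76, -0.70 and -0.64 against -0.51, -0.49 and -0.56. The covariances were -0.0649, -0.0672 and -0.0664 against -0.024, -0.0287 and -0.0333. Part of the excess may come from the shared libraries.

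Against vehicle, ESA with Fer-1 changed 0 genes in uninduced and H2O2-induced cells by edgeR (125 and 62 at an unadjusted p under 0.05; 600 and 390 with the block, which also called 0) and by DESeq2. In etoposide-induced cells it changed 1, the predicted gene Gm18584 (-2.45), named after its values were seen (132 at an unadjusted p under 0.05). It changed 0 with the block (676 at an unadjusted p under 0.05), by DESeq2, or without replicate 1 or 2 of vehicle or of ESA with Fer-1. ESA-Me with Fer-1 changed 0 genes in each state (68, 124 and 135 at an unadjusted p under 0.05; DESeq2 0 in each). With the block it changed 0, 0 and 3 (543 and 643 at an unadjusted p under 0.05 beside the 0 counts). The 3 were the early growth response gene Egr2 (-0.92), the pyruvate dehydrogenase kinase gene Pdk4 (0.91) and Gm2606 (-2.98), named after their values were seen. This comparison includes the library with Y-linked transcripts, whose mean change of immediate early genes was -0.94 against 0.02 and -0.21 in the other pairs, and leaving out a library with the block was not run for this comparison. As lists, with the block, 6, 12 and 9 of 31 differed from vehicle for ESA with Fer-1 in the 3 states and 12, 8 and 10 for ESA-Me with Fer-1. Only the endothelial markers, lower with ESA-Me and Fer-1 in uninduced cells, kept a call with an estimated correlation (adjusted p = 0.0097). Immediate early genes lay below vehicle in all 9 pairs of ESA with Fer-1 (mean log2 change -0.34 to -0.08; adjusted p = 0.00212, 0.000548 and 0.006 in the 3 states, and 0.859, 0.568 and 0.725 with an estimated correlation). NRF2 targets lay above vehicle in all 6 uninduced pairs (0.12 to 0.29; adjusted p = 0.000215 for ESA with Fer-1 and 5.62e-07 for ESA-Me with Fer-1, and 0.69 and 0.399 with an estimated correlation). The list of PPAR targets and fatty acid oxidation was higher than with vehicle in uninduced and H2O2-induced cells, with 0 of 25 members passed. This held for ESA with Fer-1 (adjusted p = 2.62e-06 and 3.89e-06) and for ESA-Me with Fer-1 (adjusted p = 5.9e-07 and 6.6e-07). With an estimated correlation the adjusted p was 0.0557 and 0.0921 for ESA with Fer-1 and 0.0687 and 0.116 for ESA-Me with Fer-1.

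Responses were also set side by side between states, in pairs of comparisons that share no library. The ESA response of uninduced cells correlated across genes at r = 0.57 with that of H2O2-induced cells and 0.46 with that of etoposide-induced cells, and the induced states at 0.49 with each other. With the block, 164 genes were higher and 39 lower with ESA in both uninduced and H2O2-induced cells, where independent lists would share 17.9 and 4.79. Likewise 69 were higher in uninduced and etoposide-induced cells (8.18 by independence) and 73 in both induced states (1.07 by independence). The induced states share preparations by number, which the latter count and the r of 0.49 do not allow for. With ESA-Me these correlations were 0.46, 0.35 and 0.30, and 42, 23 and 34 genes were higher in both.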

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

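Tests chosen only after the result was seen were the comparison of NRF2 targets over pairs, the search for a partner of a swapped library, the level of H19, the direction of ESA-responsive genes in etoposide replicate 3, every result with the GC correction, and the counts that leave out a library with the block.

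Genes whose ESA response differed between induced and uninduced cells, by the interaction with the block, are listed. For H2O2 there were 42 such genes, 133 with the GC correction. Above 0 were the sphingomyelinase gene Smpd3 (1.21), Ly6c1 (1.11), Glt8d2 (0.99) and the transcription factor gene Foxd1 (0.93), and below 0 Mocos (-2.44), Calr3 (-1.96), Gsta4 (-1.88), Them6 (-1.65), Srxn1 (-1.44), Cbr3 (-1.19) and the small heat shock protein gene Hspb8 (-0.56). For etoposide there were 120, 365 with the GC correction. Above 0 were Zbtb8b (2.21), Lrrc17 (2.14), Ptx3 (1.72), the thromboxane receptor gene Tbxa2r (1.71), Cebpa (0.97), Fdft1 (0.60) and Pdk1 (0.55), and below 0 Mocos (-2.15), Gsta4 (-1.91), Osgin1 (-1.79), Havcr2 (-1.66), Srxn1 (-1.54), Cbr3 (-1.21), Hspb8 (-0.64), Hspd1 (-0.53), Nupr1 (-0.49), the acyl-CoA dehydrogenase gene Acadl (-0.48) and the death receptor gene Tnfrsf10b (-0.37). Without 1 library, the 42 and 120 became 1 to 64 and 6 to 521, the last without etoposide vehicle replicate 3.

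The larger ESA response of uninduced cells in call counts and NRF2 targets was weighed first, which immediate early genes did not share (0.55, 0.93 and 0.69 over the uninduced pairs, 1.45, 0.72 and 0.79 with H2O2 and 1.28, 0.78 and 0.68 with etoposide). Greater depth is argued against, since the median total count of uninduced vehicle and ESA libraries was 1.13 times that of the induced ones, under the bound of 1.2 set in advance. Dependence on 1 uninduced library was found: without uninduced ESA replicate 2, the interaction with etoposide called 6 genes in place of 120. Cell state stays open, because the lowest mean log2 change of NRF2 targets over the uninduced pairs lay 0.05 below the highest of the induced pairs (a difference of -0.05, with a standard deviation of 0.25), so these libraries do not separate the states pair by pair. Uninduced and induced cells may differ in preparation, and the response may follow either.

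Replicate 3 of ESA-Me with Fer-1 in etoposide-induced cells was weighed next. It carried 92.7 CPM of 4 summed Y-linked genes where the other 4 libraries of its preparation carried 0. A swap with another library of the series is argued against by the absence of a partner: 0 other libraries lay more than 2 log2 units from the median Y-linked level of their preparation. A mixture with another library of the series stays open. A mixture should lie between others gene by gene, and 6 genes of this library lay more than 1 log2 unit outside the range of the other 44 libraries, against a highest value of 22 among the other etoposide libraries. But the noncoding RNA gene H19 stood at 372 CPM against at most 239 CPM in the other 44 libraries, which no mixture of them reaches; 1 gene does not decide. No biological explanation was tested. Without this library, Fer-1 added to ESA-Me in etoposide-induced cells called 100 genes with the block in place of 720.

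The last pattern is that exchanging the vehicle and ESA libraries of etoposide replicate 3 called 3413 genes with the block, where the libraries as given called 99. Exchanged labels are argued against by the 164 genes higher with ESA in both uninduced and H2O2-induced cells, whose median difference between the library named ESA and the library named vehicle was 0.54 with a standard error of 0.0465, above 0 in 159 of them. GC content bias between libraries stays open, because after the GC correction the exchanged libraries called 262 genes and the libraries as given 232. The counts then lay within 1.5 times of each other, while the prediction of the bias was that the exchanged libraries call no more. No biological explanation was tested.

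Splits of the same libraries were too few for a share under 0.05 in every comparison within a state, and in the interactions with 10 or 11 assignments. Of the 10 splits of 6 libraries without the block, 1 called as many genes as the real one for senescence with H2O2 (2834; highest other 0), with etoposide (2873; 0), for ESA in uninduced cells (23; 0), for Fer-1 added to ESA in uninduced (29; 0) and H2O2-induced cells (3; 0) and for ESA with Fer-1 in etoposide-induced cells (1; 0), and 2 did for Fer-1 added to ESA-Me in etoposide-induced cells (1; 348). In the comparisons whose real count was 0 by edgeR, all 10 splits did so, with the highest other at 51 for Fer-1 added to ESA and 36 for ESA-Me minus ESA, both in etoposide-induced cells, and at 0 elsewhere. All 11 assignments did so for each interaction without the block, with the highest other at 2 for ESA with H2O2, 3 for ESA with etoposide and 0 for ESA-Me.

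With the block, the real split was compared with the 3 others that part every pair. In 1 of the 4 splits as many genes were called for ESA in uninduced (3213; highest other 0) and H2O2-induced cells (240; 0), for Fer-1 added to ESA in the 3 states (3250, 677 and 383; 0), for ESA-Me in uninduced (266; 0) and H2O2-induced cells (147; 0) and for Fer-1 added to ESA-Me in uninduced (596; 0), H2O2-induced (344; 1) and etoposide-induced cells (720; 1). In etoposide-induced cells 2 of the 4 splits called as many for ESA (99; 3413) and for ESA-Me (46; 4099), and counts so far above the real one point to a structure of these samples. Of 10 assignments of the preparations to states, 1 called as many genes for the ESA interaction with H2O2 (42; 0) and 3 for that with etoposide (120; 1369, which again points to a structure of the samples), and all 10 for the ESA-Me interactions (0; 0 with H2O2 and 986 with etoposide).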

How the results depend on the processing

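DESeq2, leaving out libraries and changing the scaling, each with the block, and the GC correction were tests added after the results were seen. The cause was not tested for any change below.

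With no filter on low counts, 1876 genes passed for senescence with H2O2, 1843 with etoposide, 13 for ESA in uninduced and 3 in etoposide-induced cells, 18 for Fer-1 added to ESA in uninduced cells, and 0 for ESA with Fer-1 and for Fer-1 added to ESA-Me in etoposide-induced cells. A model of the compared groups alone gave 1283 for senescence with etoposide, 494 for ESA and 46 for ESA-Me in uninduced cells, 309 and 0 for Fer-1 added to ESA in uninduced and H2O2-induced cells, 71 and 0 for Fer-1 added to ESA-Me in uninduced and etoposide-induced cells, and 0 for ESA with Fer-1 in etoposide-induced cells. Scaling by library size gave 65 for ESA in uninduced cells and 0 for Fer-1 added to ESA in H2O2-induced cells.

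In the order uninduced, H2O2-induced, etoposide-induced, DESeq2 gave 177, 2 and 3 for ESA and 124, 18 and 10 for Fer-1 added to ESA. It gave 0 for ESA with Fer-1 and 1 for ESA-Me in etoposide-induced cells, 1 and 2 for the ESA interactions with H2O2 and etoposide, and 4 and 4 for Fer-1 added to ESA-Me in H2O2- and etoposide-induced cells. The block gave 3213, 240 and 99 for ESA, 3250, 677 and 383 for Fer-1 added to ESA, 266, 147 and 46 for ESA-Me and 596, 344 and 720 for Fer-1 added to ESA-Me. It gave 42 and 120 for the ESA interactions, 0 for ESA with Fer-1 and 3 for ESA-Me with Fer-1 in etoposide-induced cells, and 3 for ESA-Me minus ESA in uninduced cells; it moved no other count by more than 1.5 times. Senescence, not paired, is left out.

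DESeq2 with the block gave 385 and 180 for ESA in H2O2- and etoposide-induced cells, 89 and 187 for the ESA interactions, and 403, 267 and 126 for ESA-Me in the 3 states. The GC correction with the block gave 501 and 232 for ESA and 1375 and 799 for Fer-1 added to ESA in the induced states, 133 and 365 for the interactions, 692, 314 and 201 for ESA-Me and 1204, 766 and 1339 for Fer-1 added to ESA-Me. It also gave 97 (21 higher, 76 lower) in place of 3 for ESA-Me minus ESA in uninduced cells, 2 in place of 0 for ESA with Fer-1 in uninduced cells, and 1 in place of 3 for ESA-Me with Fer-1 in etoposide-induced cells. Without the block it gave 3698 and 3654 in place of 2834 and 2873 for senescence.

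Leaving out 1 library of the compared groups gave 1811 to 2446 genes for senescence with H2O2, 1828 to 2542 with etoposide, 4 to 27 for ESA in uninduced and 0 to 4 in etoposide-induced cells, 2 to 16, 0 to 7 and 0 to 10 for Fer-1 added to ESA, and, in etoposide-induced cells, 0 to 1 for ESA with Fer-1 and 0 to 6 for Fer-1 added to ESA-Me. With the block it gave 1378 to 3101, 12 to 392 and 7 to 1296 for ESA, 1513 to 3039, 62 to 836 and 50 to 535 for Fer-1 added to ESA, 1 to 64 and 6 to 521 for the ESA interactions, 3 to 149, 4 to 339 and 0 to 3321 for ESA-Me, and 69 to 278, 24 to 464 and 100 to 1083 for Fer-1 added to ESA-Me.

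Over the 10711 genes with an average log2 CPM of at least 2, correlations moved to 0.92, 0.90 and 0.77 for ESA with ESA-Me in the 3 states, and to -0.90 and -0.84 for ESA with the change on adding Fer-1 in the induced states. For ESA-Me with the change on adding Fer-1 they moved to -0.87 and -0.81 in uninduced and H2O2-induced cells. Between states they moved to 0.78, 0.65 and 0.78 for ESA and 0.73, 0.58 and 0.47 for ESA-Me (uninduced with H2O2, uninduced with etoposide, and the induced states).

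No named gene reversed its direction under the alternatives without the GC correction, nor did any list test with RLE factors, the block or an estimated correlation. DESeq2, the scalings and the GC correction with the block are given as counts alone. The balance of higher and lower genes did turn: for ESA in uninduced cells it was 20 and 3, 1489 and 1724 with the block and 2236 and 2136 with the GC correction added, and for Fer-1 added to ESA there 6 and 23, 1688 and 1562, and 2126 and 2290. Of 533 values of named genes, 225 came to pass with the block, 25 with DESeq2, where 15 more moved, 3 with no filter, 1 with scaling by library size and 36 with the compared groups alone. Calls were lost for 13 with the compared groups alone, 8 with no filter, 4 with scaling by library size, 1 with RLE factors, and 119 times over all fits that left out 1 library. With an estimated correlation, 223 called list tests lost their call and 11 kept it without the block, and 279 and 26 with it in the comparisons other than senescence. Simulated recovery at 1 log2 unit (46.27% without the block, 77.61% with it) does not test responses that differ between preparations.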

Other observations

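Tests with the GC correction and of the pairing of the inducers by replicate number were chosen after the results were seen.

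Lipid handling genes outside cholesterol synthesis moved both ways with ESA in uninduced cells, with the block. Among 25 PPAR targets and fatty acid oxidation genes, 4 rose and 5 fell: Angptl4, which encodes an inhibitor of lipoprotein lipase, rose by 2.40 ± 0.42 log2 units, the fatty acid transporter gene Cd36 by 1.52 ± 0.28 and Acadl by 0.45 ± 0.06, while Hadhb fell by 0.33 (adjusted p = 0.369 for the list). Fatty acid synthesis and desaturation genes fell for 5 of 15 members, with Fads2 at -0.62, Elovl6 at -0.48, Fads1 at -0.38 and Elovl5 at -0.31 (adjusted p = 0.0442, and adjusted p = 0.258 with an estimated correlation). Angptl4 also rose in H2O2-induced cells (2.03 ± 0.47) and did not pass in etoposide-induced cells (1.45 ± 0.45, adjusted p = 0.151).

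Of 19 secretory factors of senescence, 8 rose and 1 fell with ESA in uninduced cells, 9 and 2 adjusted over the list alone (adjusted p = 0.00782; adjusted p = 0.169 with an estimated correlation). Its member Areg, which encodes the EGF receptor ligand amphiregulin, rose with ESA by 3.45 ± 0.57 in uninduced cells (from 0.162 to 1.94 CPM, a low level) and 3.75 ± 0.71 in H2O2-induced cells, with ESA-Me by 2.72 ± 0.59 and 3.30 ± 0.74, and the related gene Ereg rose with ESA by 1.51 and 1.47. Interferon response genes fell with ESA in uninduced cells for 5 of 18 members, 6 adjusted over the list alone, including Ifi44 (-1.73 ± 0.34) and Stat2 (-0.64 ± 0.12), and contractile genes for 6 of 15, including Acta2 (-0.41) and Myl9 (-0.40). The adjusted p of these lists was 0.00156 and 0.00345, and 0.156 and 0.367 with an estimated correlation.

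Libraries of H2O2- and etoposide-induced vehicle cells with the same number deviated together, with correlations across genes of 0.62 to 0.76 against at most -0.04 for other pairs. The correlation of log2 CPM deviation with transcript GC content was 0.51 in replicate 1 of ESA-Me with Fer-1 in H2O2-induced cells and 0.22 in uninduced ESA replicate 2. In replicate 2 of etoposide-induced cells it was -0.05 with vehicle and -0.37 with ESA, -0.44 with ESA and Fer-1, -0.52 with ESA-Me and -0.53 with ESA-Me and Fer-1, so every treated library there stood apart from its vehicle.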
